A study of Mus musculus with 2 samples.

How the data were processed

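Cells from orthotopic 4T1 mammary tumours of female BALB/c mice were measured with the BD Rhapsody targeted mouse immune response panel, which counts transcripts of a fixed set of genes in single cells. The series has 4 treatment arms, and each of its 2 samples is 1 cartridge holding 2 arms told apart by sample tags. The first sample, called the no-anti-PD-1 pool here, holds isotype control and anti-Siglec-E cells under tags 1 and 2. The second, called the anti-PD-1 pool, holds anti-PD-1 and combination cells under tags 3 and 4. The labels do not say which tag carries which arm, so values are given by tag number and no value is given to a single arm.

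Each deposited table holds counts of molecules per cell and target, made by the authors with the BD Rhapsody Targeted Analysis Pipeline 1.12.1, per the file headers. Those counts had already been corrected for sequencing and amplification errors by distribution-based error correction, and cells had been assigned to tags, before deposit. Seurat 3.2.0 is named in the submitters' processing notes; the aligner and genome build are not given in the sources used here. Tag 1 was counted against another reference than tags 2 to 4: its table has 397 targets for 396 genes, 2 of them for Tigit, which were summed, and the other tables have 468 genes. The 396 shared genes were used for all 4-tag comparisons, and the 72 further genes were read in tags 2 to 4 alone. The genes only in tags 2 to 4 took 11.5% of molecules in tag 2, 8.84% in tag 3 and 9.52% in tag 4. Of the 397 targets of tag 1, 392 carry a transcript identifier, all 392 were found in GENCODE M21 (GRCm38), and 389 have the same gene name there; printed coordinates come from that annotation.

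The set minimum of 50 molecules and 10 genes removed 0 of 12018 cells, and the stricter minimum of 100 molecules and 20 genes removed 0 as well. Molecules per cell were scaled to the median total and log-transformed, and the 378 genes seen in at least 10 cells were reduced to 30 principal components. Cells were joined to their 15 nearest neighbours and clustered with the Leiden method at resolution 1.0 without batch integration (scanpy 1.11.5, igraph 0.11.9, scikit-learn 1.9.0, Python 3.11.15). This gave 16 clusters, against 12 at resolution 0.5 and 29 at resolution 2.0. Scrublet marked 0.0416% of cells as doublets, too few to count as a working call, so no doublets were removed; in the alternative the 5% highest scores per tag were removed.

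Clusters were named from marker lists fixed before the data were examined, and names are written as X-like. A name needed at least 3 markers of a class among the 10 leading genes by fold over the other cells, counting genes detected in at least 10% of the cluster. The rule for neutrophil-like clusters was set after the clusters had been seen, and its S100a8 threshold was lowered then, below the 78031 counts per 1000000 molecules of cluster 12. Clusters with at least 50000 S100a8 and under 10000 Lgals1 counts per 1000000 molecules were compared with all cells outside that group, and 2 leading neutrophil markers were enough there. This rule brings in cluster 12, which has 2 neutrophil markers among its leading genes and holds 4.69, 3.30, 6.37 and 4.89% of all cells in tags 1 to 4. Clusters with 3 or more leading markers of a second class that the first class's list lacks, or with neutrophil-level S100a8 beside another type, stayed unnamed. The CD8 T cell-like cluster kept its name with 3 NK cell markers (Klrc1, Nkg7, Gzma), as Nkg7 is on both lists. The unnamed cluster with the most Lgals1 is called the Lgals1-high cluster and is compared by that name.

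Shares carry exact Clopper-Pearson 95% intervals and summed molecules exact Poisson 95% intervals, both covering counting error only. Each pool's value is the equal-weight mean of its 2 tags. With 1 sample per group there is no replicate and no test, and tags are not replicates. Expression was compared on molecules summed per tag and class, as counts per 1000000 panel molecules (CPM), in classes with at least 30 cells in every tag; classes with at least 10 cells in every tag were added after the data were seen. A gene was measured with at least 30 molecules over the 4 tags. It was called higher or lower where both tags of a pool lay above both of the other and the nearest tags were at least 1.5-fold apart. A tag at 0 was set to a floor of 3 counts in ratios and never counted as the higher tag. Within a pool, a gene was named with at least 30 molecules over both tags and a 2-fold difference.

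Gene lists were fixed before the data were examined: antibody targets and partners, T cell checkpoint and exhaustion, cytotoxic effector, naive and memory T cell, T cell costimulation and activation, class II antigen presentation, interferon response, inflammatory cytokine, chemokine, suppressive or alternatively activated myeloid, neutrophil maturation and granule, proliferation, stress and hypoxia, and T helper transcription factors and cytokines. A list needed 3 measured members, and its median log2 ratio is given as a percentile among 10000 random panel lists of the same size matched on abundance. Named genes are the 5 highest and 5 lowest by log2 ratio among called genes of each main class, the antibody targets and Siglec genes, the 2 most abundant members of each list and its called members, and for the tag comparisons the 3 largest each way in the 3 largest leukocyte classes. Further genes are said to have been chosen after their values were seen. Some called genes and results that rest on them are not reported here. Immunoglobulin and T cell receptor genes and near-identical paralogs are uncertain.

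S100a8 alone took 18.4 to 29.1% of the shared molecules of a tag, so other genes' CPM values move with it. TMM scaling (edgeR 4.0.16, R 4.3.3) moved log2 ratios by 0.32 in neutrophil-like cells, 0.18 in the Lgals1-high cluster and 0.27 in NK cell-like cells, and ratios called relative are therefore taken from the median gene of the class; all other ratios are uncentred. Other alternatives fixed beforehand were both cell filters, both resolutions, doublet removal, pooling the tags, leaving out each tag, all cells as denominator, other molecule minimums and a 2-fold rule. Added after the data were seen were the neutrophil-like class without cluster 5 or cluster 12, scaling without S100a8 and S100a9, and each named gene without its richest cell. To compare shares of cells with a molecule, each cell was thinned to 300 molecules.

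The size rule was tested on simulated Poisson counts drawn from each class's mean profile and tag totals over 396 genes, with 50 genes changed 2-fold and 50 changed 3-fold. It recovered 86% of 2-fold and 94% of 3-fold changes in neutrophil-like cells, 88% and 98% in monocyte/macrophage-like cells, and 76% and 92% in the Lgals1-high cluster. It called 2 of 214, 2 of 244 and 1 of 131 unchanged genes there. The simulation holds no variation between animals or cartridges, so it shows recovery at this depth only. Computations used numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures matplotlib 3.10.9.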

Results

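The study asked how antibody blockade of Siglec-E, PD-1 or both alters the cells of 4T1 tumours. 4T1 is a mouse mammary carcinoma line that grows in BALB/c mice and recruits many neutrophils. Siglec-E is an inhibitory sialic acid receptor of mouse myeloid cells, and PD-1, encoded by Pdcd1, is an inhibitory receptor of activated T cells. Mice of 8 weeks received tumour cells in the mammary fat pad, and treatment began at 7 days, at about 70 mm3. Each of the 4 arms had 6 mice, of which 2 tumours were taken for single cells. EPCAM-positive and EPCAM-negative fractions were recombined 1 to 4, so the share of epithelial cells was set by the experimenters. The 2 cartridges gave 4 tag populations, with isotype control and anti-Siglec-E cells under tags 1 and 2 and anti-PD-1 and combination cells under tags 3 and 4.

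Tags 1 to 3 held 2430, 1515 and 6620 cells and tag 4 the rest of 12018, with shared-gene totals of 5318288, 2993684, 12416134 and 3074544 molecules. Median molecules of shared genes per cell were 1463, 1325, 1262 and 1419, and median genes per cell 83, 84, 78 and 83. S100a8, a calcium-binding alarmin of neutrophils, took 18.4, 21.2, 29.1 and 22.9% of those molecules. Ferritin heavy chain, Fth1, took a further 11.9, 12.3, 15.4 and 13.6%.

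Neutrophil-like cells made up 7 of the 16 clusters, most of them led by S100a8, S100a9, Cxcr2 and Cxcr1. Monocyte/macrophage-like cells (953 cells) were led by C1qa, Arg1, C1qb and Trem2, CD8 T cell-like cells (261) by Cd8b1, Cd8a, Gzmk and Pdcd1 beside the NK cell genes Klrc1 and Gzma, and regulatory T cell-like cells (345) by Cd4, Foxp3, Il2ra and Ctla4. NK cell-like cells (136) were led by Klra7, Eomes and Xcl1, and B cell-like cells (72) by Cd79a and Cd79b. The Lgals1-high cluster (772 cells) was led by Lgals1, Lmna, Spp1 and Fn1 and did not meet the naming rule. In it Epcam, an epithelial adhesion gene counted in tags 2 to 4 alone, reached 8852, 10782 and 10057 CPM in tags 2, 3 and 4, against 58.0, 30.003 and 25.7 in neutrophil-like cells. E-cadherin, Cdh1, stood at 2722, 2786 and 2625 and mesothelin, Msln, at 2711, 2567 and 2855.0 CPM in the cluster.

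A further 3 clusters stayed unnamed. Cluster 1, with mast cell or basophil genes (Il4, Cpa3, Fcer1a) beside dendritic cell genes (Ccr7, Fscn1, Il12b), held 0.494, 0.660, 0.619 and 0.964% of all cells in tags 1 to 4. Cluster 3, led by Il33, Cd34 and Lrrc32, held 2.84, 2.64, 1.22 and 2.48%. Its S100a8 stood at 89607 CPM, above the 78031 of neutrophil-like cluster 12, so it may hold neutrophils or their RNA as well. Cluster 11 carried T cell genes (Trdc, Cd3e, Cd8a) together with S100a8 at the level of neutrophil-like cells and held 0.453, 0.462, 1.30 and 2.13%. The Lgals1-high cluster held 10.3, 6.53, 3.88 and 11.4% of all cells, shares that the recombination of fractions can affect. The stated 1 to 4 ratio was the same for both samples, so it does not by itself give the differences between tags.

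The first comparison asked which leukocytes differed in share between tumours given anti-PD-1, alone or combined, and tumours given none. CD8 T cell-like cells had a higher share in the anti-PD-1 pool, 4.22% of named leukocytes on average against 0.996%, a ratio of 4.23. Regulatory T cell-like cells stood at 4.90% against 1.93% and B cell-like cells at 0.962% against 0.328%. No other CD4 T cell class was named, and Foxp3 was found in 37.0, 28.6, 31.7 and 42.3% of regulatory T cell-like cells in tags 1 to 4. The class may therefore hold other CD4 T cells, which were not told apart. Neutrophil-like cells, the bulk of all leukocytes in every tag, had a lower share of named leukocytes, 78.9% against 85.6%, though the pools overlapped when all cells were the denominator.

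By tag, CD8 T cell-like cells made up 0.815% (95% exact interval 0.475 to 1.30; 17 cells), 1.18% (0.674 to 1.90; 16 cells), 2.55% (2.17 to 2.98; 157 cells) and 5.88% (4.62 to 7.36; 71 cells) in tags 1 to 4. Regulatory T cell-like cells made up 1.29% (0.854 to 1.88), 2.58% (1.80 to 3.56), 3.33% (2.90 to 3.81) and 6.46% (5.14 to 8.00). The intervals of tags 2 and 3 overlap for regulatory T cell-like cells and not for CD8 T cell-like cells. Neutrophil-like shares were 86.3% (84.8 to 87.8), 84.9% (82.9 to 86.8), 84.5% (83.6 to 85.4) and 73.2% (70.6 to 75.7), so the difference of the pools, -6.76 points, came mostly from tag 4 and was -1.13 points without it. As percent of all cells they stood at 74.2, 76.2, 78.6 and 60.8, so tag 3 lay above tags 1 and 2 and the pools overlapped, with a difference of -5.46 points. B cell-like shares were 0.287, 0.368, 0.764 and 1.16%, on 6, 5, 47 and 14 cells. NK cell-like cells, at 0.671, 1.32, 1.43 and 1.33%, were 0.380 points higher in the anti-PD-1 pool, and 0.0532 points without tag 1; as percent of all cells (0.576, 1.19, 1.33 and 1.10) the pools overlapped. Monocyte/macrophage-like cells, at 10.6, 9.64, 7.42 and 11.9%, overlapped between the pools, and their difference of -0.437 points was 0.0382 without tag 1 and 1.82 without tag 3.

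**Figure D1:**
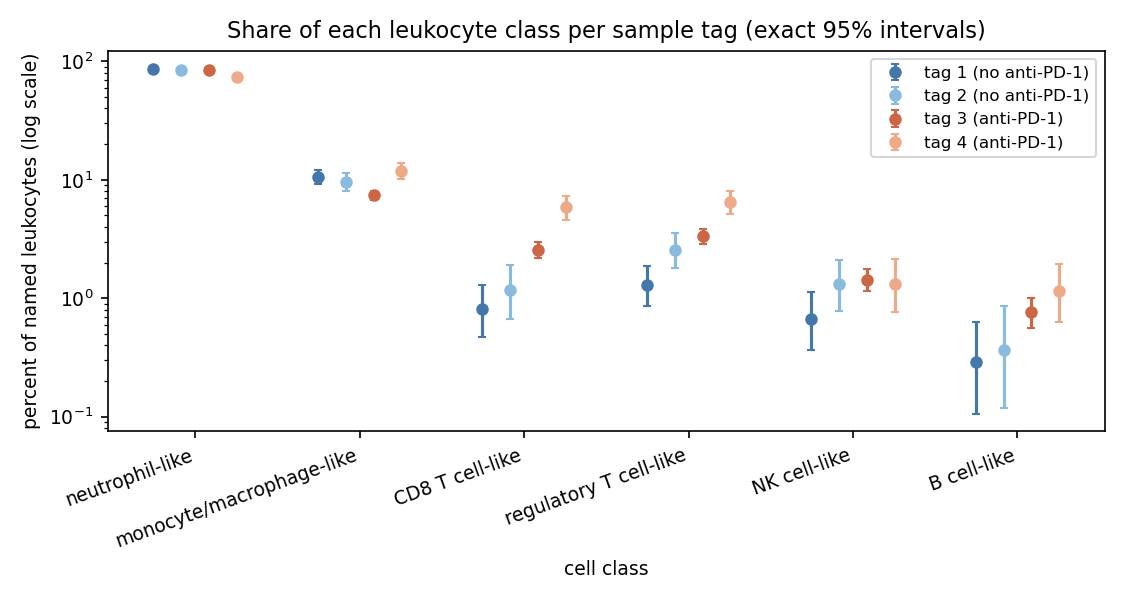
Share of each leukocyte class among named leukocytes (percent, log scale) for each sample tag, with exact 95% binomial intervals as bars. CD8 T cell-like shares of 2.55 and 5.88% in tags 3 and 4 lie above the 0.815 and 1.18% of tags 1 and 2, whereas monocyte/macrophage-like shares overlap.

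Each pool is 1 cartridge of 2 arms, so the share differences have no replicate and cannot be separated from the cartridge. By chance alone 1 in 3 orderings of the tags separates the pools.

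Within neutrophil-like cells, several inflammatory genes were lower in the anti-PD-1 pool and few genes were higher. Interleukin 1 beta, Il1b, stood at 592 (565 to 621), 584 (549.7 to 619), 271 (260.0 to 282) and 278 (253 to 305) CPM in tags 1 to 4 (exact Poisson 95% intervals), a log2 ratio of -0.79 relative to the median gene. The chemokine Cxcl1 was lower (588, 601, 233 and 333), as were the macrophage-associated genes Spp1 (1679, 2263, 854 and 653) and Arg1 (161, 131, 85.9 and 14.3). Galectin 1, Lgals1, was lower at 1752, 1771, 443 and 309.8. In tags 2 to 4 the level of Epcam in neutrophil-like cells was 0.656, 0.278 and 0.256% of that in the Lgals1-high cluster, that of Msln 0.626, 0.308 and 0.241% and that of Cdh1 1.35, 1.22 and 1.33%. Over these 3 markers, the same percent of the cluster's RNA would make up 0.390 to 0.518 of the difference of Lgals1, 0.511 to 0.732 of that of Gata3 and 0.442 to 0.708 of that of Cxcl1. It would make up 0.0707 to 0.189 of that of Spp1 and 0.0002 to 0.0004 of that of Il1b. Macrophage markers, chosen after their values were seen, were low in these cells: C1qb, called lower, stood at 30.6, 32.8, 13.2 and 3.12, Trem2 at 12.6, 10.6, 4.03 and 8.10 and C1qa at 6.46, 6.35, 4.71 and 0.623. Macrophage RNA at the level of these markers would make up 0.0852 to 1.26 of the difference of Arg1, depending on the marker. Under TMM scaling Il1b, Spp1 and Lgals1 stayed called, whereas the nearest tags of Cxcl1 and Arg1 were 1.40 and 1.20-fold apart and their calls ended. Neutrophil elastase, Elane, was higher (23.1 (18.0 to 29.3), 65.6 (54.6 to 78.2), 267 (256 to 278) and 122 (105 to 139.9)), as was the chitinase-like gene Chil3 (757, 650.3, 1137 and 1545). Without cluster 5 the uncentred log2 ratio of Elane was 0.07 in place of 2.13, and that of Chil3 reversed to -0.21 from 0.93.

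Of 316 measured genes in neutrophil-like cells, 6 were higher and 43 lower, and the pools lay apart in 69.9% of genes where chance orderings give 1 in 3. Genes of a class share the same tag totals, so 1 common shift can raise that percent. It therefore does not count separate differences, here or in the other classes. The median gene had a log2 ratio of -0.31, and S100a8 itself stood at 316785, 319908, 391129 and 407018 CPM; ratios called relative are taken from that median, and the others are uncentred. Under TMM scaling 11 were higher and 21 lower, so the higher share of called genes was 34.4% against 12.2%. The genes with the largest ratios upwards were Fcer1a, Cpa3, Elane, Ube2c and Chil3. Fcer1a and Cpa3 are mast cell and basophil genes, and 1 cell held 62.3% and 63.3% of their molecules. The ubiquitin-conjugating cell cycle gene Ube2c stood at 20.4, 16.4, 94.8 and 44.9. The largest ratios downwards were those of Il6 (26.2, 29.6, 2.58 and 3.12), the interleukin 3 receptor subunit Il3ra (10.5, 19.0, 0.56 and 2.49), the chemokine Ccl17, Lgals1 and the transcription factor Gata3 (12.9, 10.1, 3.36 and 1.87); 1 cell held 37.3% of Ccl17.

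By list, of 13 chemokines measured in neutrophil-like cells 4 were lower (Cxcl1, Cxcl16, Ccl17, Xcl1) and 0 higher, with the median at percentile 1.1 of random lists. Under TMM scaling Ccl17 alone of these stayed called, with Cxcl1, Cxcl16 and Xcl1 at 1.40, 1.22 and 1.42-fold between the nearest tags. Macrophage RNA would make up 0.0907 to 1.08 of the difference of Cxcl16, depending on the marker. The most abundant chemokines, Cxcl2 and Ccl3, had relative log2 ratios of -0.16 and -0.13 and passed no rule. Among inflammatory cytokines 4 of 9 were lower (Il1b, Il1rn, Il18, Il6) at percentile 3.1; the interleukin 1 receptor antagonist Il1rn, the most abundant, stood at 17914, 18219, 11517 and 11271, and Tnf at a relative 0.00. Il1b and Il6 stayed called under TMM scaling, and Il1rn and Il18, at 1.24 and 1.32-fold, did not. Class II antigen presentation had 2 of 8 lower, H2-Aa (598, 777, 327 and 277) and H2-Ab1, while H2-Eb1 stood at 116, 133, 165 and 141. The suppressive myeloid list had Chil3 higher and Arg1, Nt5e and Spp1 lower among 14 members. Neutrophil maturation and granule genes had Elane higher among 7, with S100a8 and S100a9 at relative log2 ratios of 0.64 and 0.19.

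Interferon response genes in neutrophil-like cells had 0 of 5 called, with the median 0.37 above the class median (percentile 98.7), Cd274 at 0.05 and Irf7 at 0.57. Proliferation genes had Ube2c higher and the replication clamp gene Pcna (493, 539, 246 and 219) lower among 8; their median lay 0.57 above the class median, and its uncentred log2 ratio of 0.26 was -0.73 without cluster 5. The stress and hypoxia list had Dusp2 lower among 8, with its most abundant members Hmox1 and Dusp1 at relative -0.19 and -0.10. Of the T cell lists, the checkpoint list had Entpd1 (4306, 4358, 2829 and 2831) and Havcr2 lower among 7, and the cytotoxic list Eomes lower among 11. Under TMM scaling H2-Aa, H2-Ab1, Pcna and Eomes stayed called, and Nt5e, Dusp2, Entpd1 and Havcr2, at 1.43, 1.20, 1.19 and 1.26-fold, did not. The calls of Eomes and H2-Ab1 rest on few molecules. In tags 2 to 4 Eomes stood at 11.6, 2.13 and 0 CPM and H2-Ab1 at 6.35, 2.46 and 1.87. Eomes is also a leading gene of NK cell-like cells, and their RNA in neutrophil-like cells was not tested.

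The clusters within the neutrophil-like class shifted as well. Cluster 5, with the most S100a8 and with Chil3 among its leading genes, made up 0.721, 1.13, 4.52 and 4.98% of neutrophil-like cells in tags 1 to 4. Cluster 2 made up 15.04, 14.9, 21.6 and 23.4%, and cluster 6 17.5, 17.9, 12.04 and 12.1%. Without cluster 5 the number of higher genes was 3.

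Monocyte/macrophage-like cells of the anti-PD-1 pool had more of the class II gene H2-Eb1 and less of the complement gene C1qa, the latter chosen after its value was seen. H2-Eb1 stood at 10018 (9817 to 10223), 11065 (10769 to 11368), 23623 (23396 to 23853) and 20079 (19697 to 20467) CPM in tags 1 to 4 and C1qa at 4628 (4492 to 4768), 3912 (3736 to 4094), 1898 (1834 to 1964) and 1334 (1237 to 1437). Heme oxygenase, Hmox1, was lower (16484, 16794, 8904 and 9292), and the lipid carrier Apoe was higher (41.4, 37.8, 80.9 and 68.8) from a low level. The lymphoid or dendritic cell integrin Itgae was higher too (88.2, 145, 440.5 and 371).

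Of 344 measured genes in this class, 7 were higher and 17 lower, and the pools lay apart in 43.6% of genes against 1 in 3 by chance ordering. Higher genes were 29.2% of those called, 45.5% under TMM scaling (10 higher, 12 lower) and 12.5% after removal of the highest doublet scores (3 higher, 21 lower). Most calls were not the same ones after that removal: 2 of the 7 higher (Btla and Itgae) and 7 of the 17 lower (C1qa, Cd72, Fcna, Gata3, Il3ra, Nrp1 and Pcna) were kept. Genes that were no longer called kept their direction, some with little change in size. Their uncentred log2 ratios after removal were H2-Eb1 0.94 (from 1.05), Apoe 0.59 (from 0.92), Cd8a 1.99 (from 2.03), Cd8b1 1.69 (from 1.68), Hmox1 -0.67 (from -0.87) and Ada -2.34 (from -1.70). The same held for H2-Ab1 -0.80 (from -0.87), Il18 -0.59 (from -0.66), Jun -0.53 (from -0.75), Ccr7 -1.01 (from -1.17) and Bach2 -1.10 (from -1.02), and H2-Ob and Tgfb1 dropped below the molecule minimum, so they had no call. The other higher genes were H2-Ob, Btla and the T cell coreceptor genes Cd8a (107, 94.5, 248 and 573) and Cd8b1 (112, 84.0, 237 and 390.0). Cells with at least 3 Cd8a molecules, 38 in number, held 98.7% of the Cd8a of the class and had a median of 5562 molecules against 2802 for the class. The largest ratios downwards were those of Il3ra (122 (101 to 147), 158 (124 to 198), 10.3 (6.12 to 16.3) and 7.65 (2.08 to 19.6)), Tgfb1, adenosine deaminase Ada, the ficolin gene Fcna (955, 563, 292 and 214) and Cd72 (1207, 1679, 653 and 434). In Tgfb1 the counts were small (13, 10, 7 and 3 molecules), and 1 cell held 20.2% of Ada.

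The class held dendritic cell-like cells as well, which separated at resolution 2.0. They were 33.9, 40.9, 42.6 and 56.2% of the macrophage-like and dendritic cell-like cells of tags 1 to 4 there, and their C1qa stood at 46.0, 0, 63.3 and 87.3 CPM. Of these 75, 54, 199 and 82 cells, Cd14 was found in 72, 53, 190 and 82 and Lyz2 in 69, 51, 183 and 78. H2-Aa was found in 51, 39, 138 and 65 of them, but Flt3 in 7, 10, 49 and 18. The dendritic cell name is therefore uncertain, and many of these cells may be monocyte-like. In the macrophage-like cells left, C1qa stood at 5737, 5453, 2441 and 2137, Fcna at 1181, 779, 377 and 267 and Cd72 at 1462, 2243, 771 and 578, all still lower, as was Hmox1. H2-Eb1 was still higher in them (9560.2, 10484, 22341 and 17325) and stood at 12709, 12296, 26831 and 24029 in the dendritic cell-like cells. At that resolution 6 of the 7 higher and 11 of the 17 lower calls were kept, and H2-Ob and Tgfb1 were below the molecule minimum. Not called there, in the same direction, were Ada -1.65 (from -1.70), Bach2 -0.63 (from -1.02), Nrp1 -0.59 (from -0.71) and Pcna -0.63 (from -0.83).

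Among lists in monocyte/macrophage-like cells, class II antigen presentation had H2-Eb1 higher and H2-Ab1 (366, 359, 238 and 159) lower of 8 members, with H2-Aa at a relative 0.47 and the median at percentile 99.1. The antibody target, T cell checkpoint and cytotoxic lists stood about as high in this class, at percentiles 98.99, 98.4 and 97.99, and the T helper list at 1.66. The class includes the 38 cells with at least 3 Cd8a molecules, which carried Cd3 as well. Their part in these lists was not tested, so the percentiles need not describe macrophages. The suppressive myeloid list had Apoe higher and Tgfb1 lower of 18; its most abundant members Arg1 and S100a8 stood at relative -0.38 and 0.33. Of 13 chemokines 0 were called, with Cxcl2 at 0.21 and Cxcl1 at -0.61. Inflammatory cytokines had Il18 lower of 9, with Il1a at 0.27 and Il1rn at -0.08. Interferon response genes had 0 of 5 called (Cd274 0.11, Cxcl10 -0.12). The stress and hypoxia list had Hmox1 and Jun lower of 8, proliferation had Pcna (1828, 1798, 963 and 1070.5) lower of 8, and the T helper list had Gata3 lower of 9. The checkpoint list had Btla higher of 7, and the naive and memory list Ccr7 (990.5, 1174, 656 and 306) and Bach2 lower of 10. Under TMM scaling H2-Ab1, Il18, Jun and Ccr7, at 1.34, 1.46, 1.43 and 1.42-fold between the nearest tags, were not called.

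In the Lgals1-high cluster, class II genes and the interferon-induced genes Irf7 and Oas2 were higher in the anti-PD-1 pool. H2-Eb1 stood at 1341 (1269 to 1415), 2709.9 (2548 to 2879), 7231 (7045 to 7421) and 8998 (8741 to 9260.3) CPM in tags 1 to 4 and H2-Aa at 3899.6, 7749.7, 12258 and 14448. The interferon regulatory gene Irf7 (661 (611 to 714), 602 (528 to 685), 1333 (1254 to 1416) and 1356 (1257 to 1459.9)) and the antiviral gene Oas2 (52.9, 44.0, 136 and 118) were higher. The chemokine Ccl5 (109.8, 103, 318 and 1049.7), the cytokine receptor gene Il12rb1 (88.4, 101, 245 and 323) and the actin-bundling gene Fscn1 (867, 879, 2344 and 2407) were higher as well. Ccl5 is also the most abundant cytotoxic effector gene of CD8 T cell-like and NK cell-like cells. Whether RNA or cells of those classes in the cluster gave Ccl5 or Il12rb1 was not tested. Pcna (4264, 3258, 1848 and 2035) and the topoisomerase Top2a (3193, 2423, 1539.7 and 1590.0) were lower, but not called under TMM scaling (1.496 and 1.39-fold between the nearest tags), where all higher calls held.

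**Figure D2:**
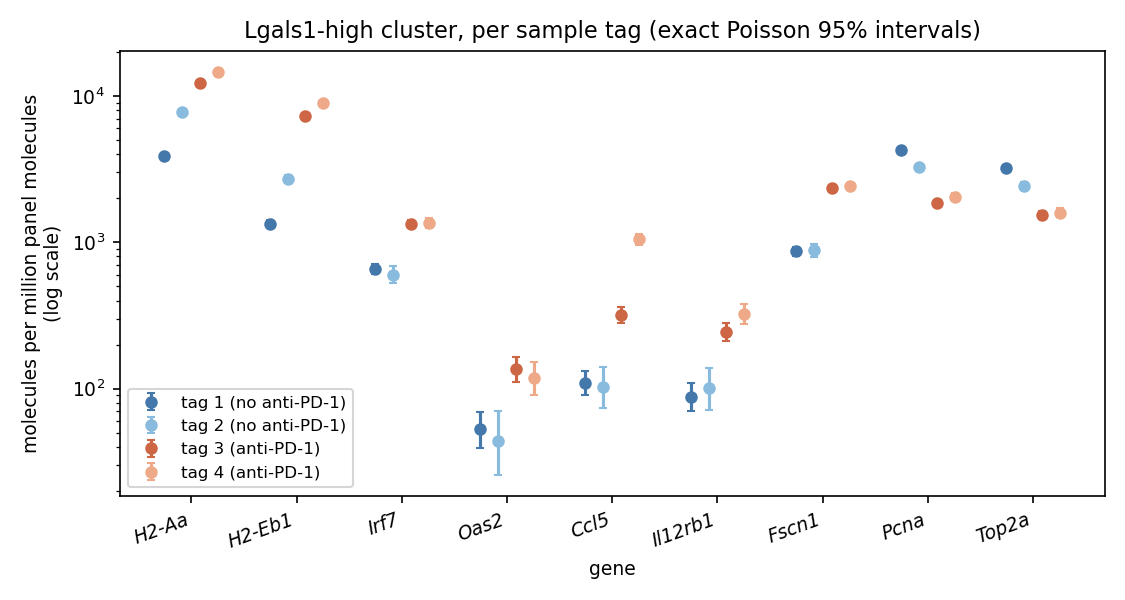
Counts per 1000000 panel molecules (CPM, log scale) of 9 genes in the Lgals1-high cluster for each sample tag, with exact Poisson 95% intervals as bars. The points of tags 3 and 4 lie above those of tags 1 and 2 for H2-Aa, H2-Eb1, Irf7, Oas2, Ccl5, Il12rb1 and Fscn1, and below them for Pcna and Top2a.

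Of 235 measured genes in the cluster, 8 were higher and 30 lower, and the pools lay apart in 65.1% of genes against 1 in 3 by chance ordering. Under TMM scaling 14 were higher and 19 lower, so higher genes were 42.4% of those called against 21.1%; the median gene stood at an uncentred -0.26. At resolution 0.5 all 8 higher but only 15 of the 30 lower calls were kept, among 9 higher and 37 lower. The largest ratios downwards were those of Ighm, Igkc, Ccr7, Il3ra (38.6, 36.2, 1.27 and 0) and Lrrc32. A single cell held 93.8%, 81.2%, 56.0% and 62.3% of the molecules of Ighm, Igkc, Ccr7 and Lrrc32, and immunoglobulin genes are uncertain in any case.

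Both class II genes called were higher among 8 of their list, and the list's median lay 1.15 above the class median (percentile 99.9). Proliferation genes had Pcna and Top2a lower of 8, at percentile 0.74. Inflammatory cytokines had Il1rn (605, 584, 137 and 124), Il6 and Il18 lower of 6, and chemokines had Ccl5 higher and Ccl2, Ccl3 and Cxcl2 (1364, 1414, 787 and 476) lower of 13; the uncentred log2 ratio of Ccl3, -0.88, reversed to 0.31 at resolution 0.5. Ccl3, Cxcl2 and Il18 were not called under TMM scaling (1.26, 1.44 and 1.43-fold). Other genes of neutrophils, chosen after their values were seen, were lower in the cluster as well: Entpd1 (184, 122, 59.6 and 32.9), Ccr10 (19.3, 18.1, 5.07 and 5.81) and Trem1 (178, 209, 44.4 and 63.9). S100a8 there stood at 6437, 6074, 4334 and 5709 and Cxcr2 at 24.4, 5.17, 5.07 and 0, neither called. The hypoxia regulator Hif1a (3876, 2821, 1623 and 1659.7) was lower, 1 of 8 in its list, in which Egr1 and Dusp1 stood at relative 0.39 and 0.41. S100a9 (260.2, 212, 59.6 and 67.8) was lower of 14 suppressive myeloid genes, whose most abundant members Spp1 and Lgals3 stood at 0.46 and -0.15.

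A set of genes was lower in the anti-PD-1 pool in several classes. The 5 genes Gata3, Il18, Il3ra, Nrp1 and Pcna were lower in all 3 classes, and 14 genes were lower in more than 1. Under TMM scaling Gata3 and Il3ra stayed called in all 3, Il18 in none, Nrp1 in the Lgals1-high cluster alone and Pcna in the other 2. Il3ra had relative log2 ratios of -2.97, -3.87 and -3.14 in neutrophil-like cells, monocyte/macrophage-like cells and the Lgals1-high cluster, and Pcna -0.84, -0.74 and -0.69. Gata3 is also among the leading genes of the Lgals1-high cluster, where its relative ratio was -0.79, against -1.83 and -1.23 in the other classes. Monocyte/macrophage-like cells held Epcam at 701, 1005 and 270 CPM and Cdh1 at 592, 753 and 371 in tags 2 to 4. How much of their Gata3 could be RNA of the cluster was not tested, so the 3 classes need not be separate observations.

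**Figure D3:**
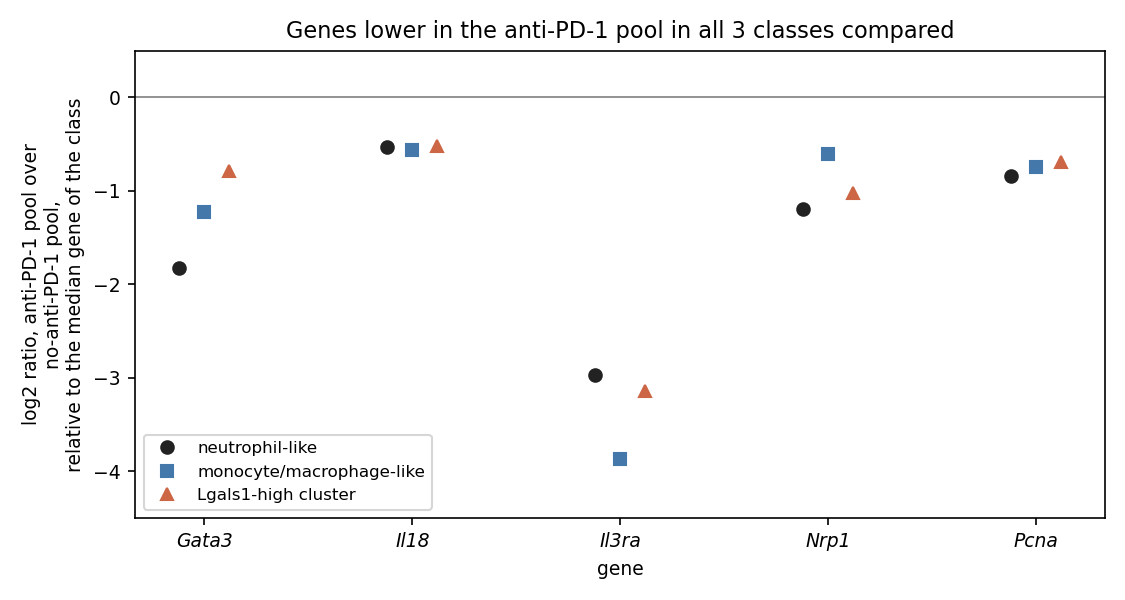
Log2 ratio of the anti-PD-1 pool over the no-anti-PD-1 pool, relative to the median gene of each class, for the 5 genes lower in all 3 classes compared, with 1 symbol per class and no interval. Il3ra lies between -2.97 and -3.87 in the 3 classes, below the other 4 genes.

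CD8 T cell-like cells of the anti-PD-1 pool had more Tigit and Prf1 transcripts, whereas Pdcd1 and Ctla4 lay within the spread of the tags. Tigit, an inhibitory receptor, stood at 2224 (1737 to 2806), 2288 (1787 to 2886), 4113 (3819 to 4423) and 4306 (3887 to 4757) CPM in tags 1 to 4. The perforin gene Prf1 stood at 94.0, 0, 311 and 356 (3, 0, 55 and 32 molecules) and the transcription factor Lef1 at 157, 161, 424 and 345. Granzyme B, Gzmb, stood at 34777, 58560.0, 23535 and 22963 and was not called: the pools lay apart, but the nearest tags were 1.48-fold apart, under the 1.5-fold of the rule. Of 244 measured genes 10 were higher and 11 lower, on only 17 and 16 cells in tags 1 and 2, with the pools apart in 43.9% of genes against 1 in 3 by chance ordering.

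In these cells the checkpoint list had Tigit higher of 7, with its most abundant members Pdcd1 and Ctla4 at relative log2 ratios of 0.07 and -0.16. Cytotoxic effector genes had Prf1 higher of 14 (Ccl5 0.80, Nkg7 0.51). Naive and memory genes had Lef1 higher of 9 at percentile 99.4 (Tcf7 0.56, Cd44 0.09). Of 11 costimulation and activation genes 0 were called (Tnfrsf9 -0.38, Cd69 -0.72). The class II genes H2-Aa and H2-Eb1 were higher, with 1 cell holding 37.5% and 46.2% of their molecules, and H2-Aa reversed to an uncentred log2 ratio of -0.85 at resolution 0.5. The stress genes Jun and Hmox1 were lower (689, 1096, 379 and 334 for Hmox1), and the lower calls of Il6 and Ccl2 came from 1 cell of tag 2 with 96.9% and 96.5% of the molecules.

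Regulatory T cell-like cells of the anti-PD-1 pool had fewer Klrg1 and Ccr7 transcripts. As this class may hold other CD4 T cells, a different mix of cells within it was not told apart from a change in regulatory T cells. Klrg1, a marker of differentiated lymphocytes, stood at 4447 (3572 to 5473), 2781 (2236 to 3418), 1195 (1019 to 1394) and 1214 (951 to 1526) CPM, and the homing receptor Ccr7 at 14991, 12389.9, 6849.5 and 6649. Ctla4 (18189, 15139.8, 16089.8 and 13681) and Foxp3 (3648, 3708, 2325 and 3042) passed no rule. Of 258 measured genes 10 were higher and 11 lower, with the pools apart in 34.1% of genes, close to the 1 in 3 of chance orderings. T helper genes had Il13 and Il5 higher and Gata3 and Bcl6 lower of 11, but 1 cell of tag 3 held 95.3% of Il13. NK cell-like cells had the transcription factors Eomes (12429.6 (10369.7 to 14779), 14063 (12357 to 15938), 5227 (4739 to 5751) and 5299 (4359 to 6381)) and Tcf7 (5729, 3387, 1986 and 1002) lower, among 5 higher and 8 lower of 198 genes, on as few as 14 cells.

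The antibody targets themselves were read in every class. Pdcd1 (chromosome 1, 94038305 to 94052553, minus strand, a protein-coding transcript of 5 exons in GRCm38) stood at 10119.7 (9046 to 11286), 5898 (5074 to 6817), 7655 (7252 to 8074) and 9023 (8412 to 9666) CPM in CD8 T cell-like cells and at 1749, 1792, 2545 and 3142 in regulatory T cell-like cells. In monocyte/macrophage-like cells Pdcd1 stood at 99.9, 134, 173 and 443, and the part of the cells with Cd8a and Cd3 in this was not tested. It was called in none of the 5 classes where it was measured, and the Lgals1-high cluster had under 30 molecules. The ligand gene Cd274 (chromosome 19, 29367455 to 29388095, plus strand, 7 exons) stood at 6081 (5993 to 6171), 5876 (5767 to 5986), 5094 (5048 to 5141) and 4891 (4784 to 5001) in neutrophil-like cells and at 3428, 4082, 3812 and 3779 in monocyte/macrophage-like cells, with no call. Siglece was counted in tags 2 to 4 alone and stood at 401, 554 and 546 in neutrophil-like cells and 127, 115 and 133 in monocyte/macrophage-like cells. Cd33, another sialic acid receptor gene, stood at 1325, 1326, 1311 and 1303 in neutrophil-like cells of tags 1 to 4. Siglecf in neutrophil-like cells stood at 119, 74.5 and 74.4, Siglecg in monocyte/macrophage-like cells at 78.3, 48.1 and 34.2 and Siglec1 there at 63.3, 57.4 and 66.7 in tags 2 to 4. In B cell-like cells Siglecg stood at 4470.0, 2594 and 5130.3 and Siglech at 7982, 14996 and 6136 in those tags, on 5, 47 and 14 cells. Siglech is also on the fixed marker list of plasmacytoid dendritic cells. Whether such cells or their RNA in the class gave it was not tested. Cd22 in monocyte/macrophage-like cells stood at 14.9, 31.5, 29.2 and 15.3 in tags 1 to 4. Pdcd1lg2 is in neither panel and was not measured.

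Other called genes lie elsewhere in the genome. H2-Aa (34282744 to 34287823, minus strand) and H2-Eb1 (34306017 to 34316199, plus strand) are neighbours on chromosome 17, in the class II region. Irf7 lies on chromosome 7 (141262706 to 141266421, minus strand, 10 exons), Il3ra on chromosome 14 (14346275 to 14355490, plus strand, 12 exons) and Itgae on chromosome 11 (73090583 to 73147446, plus strand, 31 exons).

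The 2 tags of each pool differ by anti-Siglec-E treatment in an order the labels do not state. Tag 4 had 2.31 times the CD8 T cell-like share of tag 3 and 1.94 times its regulatory T cell-like share, with a lower neutrophil-like share. Tag 2 had 1.99 times the regulatory T cell-like share of tag 1, with intervals that overlap slightly. The scavenger receptor Cd163 in monocyte/macrophage-like cells was lower in tag 2 than in tag 1 and lower in tag 4 than in tag 3 (278, 81.9, 354 and 21.027 in tags 1 to 4). Chil3 in these cells was higher in tag 4 (3657) than in tag 3 (672), and Ccl17 lower in tag 2 (42.0) than in tag 1 (733).

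By the 2-fold rule, tag 2 against tag 1 gave 22 genes higher and 3 lower of 272 in neutrophil-like cells, and 52 higher and 8 lower of 318 in monocyte/macrophage-like cells. Tag 4 against tag 3 gave 11 higher and 29 lower of 296, and 35 higher and 14 lower of 327. In neutrophil-like cells the largest log2 ratios of tag 2 over tag 1 were those of Blnk (6.16), Cd7 (4.68) and Cd8b1 (3.35) upwards and H2-DMb2 (-1.95), Cd34 (-1.27) and Junb (-1.19) downwards. For tag 4 over tag 3 they were Mzb1 (3.25), Iglc3 and Cd8a (2.43) upwards and Tigit (-3.48), Ighg1 and Cd79a downwards, all lymphocyte genes at few molecules. In monocyte/macrophage-like cells Il17a (8.11; 63.9% in 1 cell), Trdc (6.48) and Pou2af1 were highest and Ccl17 (-4.13), Junb (-2.34) and Cd163 (-1.76) lowest in tag 2. In tag 4 Klra5 (2.82), Chil3 (2.44) and Elane (2.21) were highest and Cd163 (-4.07), Igkc and Il12b lowest. In regulatory T cell-like cells Xcl1 (-7.70), Cd8a and Csf2 (-4.12) were lower and H2-Aa, Top2a (2.99) and Mki67 (2.77) higher in tag 2, on 27 and 35 cells. There Il13, Il4 and Il10 (-1.93) were lower and Mgst1, Itgax and H2-Eb1 (2.48) higher in tag 4 than in tag 3. Tag 1 was counted against another reference than tag 2, so that pair differs by reference as well as by arm.

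Pdcd1, Gzmb, Tigit and Mki67 were also read as shares of CD8 T cell-like cells with a transcript. A Pdcd1 molecule was found in 64.7, 62.5, 65.0 and 78.9% of CD8 T cell-like cells of tags 1 to 4, and in 52.9, 56.2, 52.9 and 69.0% after thinning to 300 molecules. Gzmb was found in 88.2, 81.2, 70.1 and 71.8% (82.4, 62.5, 61.9 and 64.8% thinned), Tigit in 76.5, 75.0, 84.1 and 80.3% (52.9, 50.0, 54.8 and 56.3%), and the proliferation gene Mki67 in 41.2, 25.0, 24.8 and 39.4% (35.3, 18.8, 16.1 and 25.4%). In B cell-like cells, as background, Pdcd1 was found in 4.17%, Gzmb in 1.39%, Tigit in 2.78% and Mki67 in 8.33% of 72 cells, and after thinning in 4.55, 0, 3.03 and 9.09% of 66. Median depth was 1065, 1118, 977 and 967 molecules in the CD8 T cell-like cells of the tags and 588 in B cell-like cells; thinning left out 0, 0, 2 and 0 of the former. The exact intervals of all 4 tags overlap for each of these genes.

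Foxp3 was found in 37.0, 28.6, 31.7 and 42.3% of regulatory T cell-like cells (26.9, 22.9, 27.4 and 34.7% thinned), against 0 of 72 B cell-like cells, at median depths of 654, 840, 553 and 620 molecules; thinning left out 1, 0, 15 and 3 cells. Cd274 was found in 90.8, 90.6, 87.96 and 88.9% of neutrophil-like cells (70.5, 69.6, 66.5 and 67.8% thinned, with 2, 3, 12 and 1 cells left out), against 55.1% of NK cell-like cells (31.1% thinned), at median depths of 1202.5, 1173, 1221 and 1210.5 against 743 molecules.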

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

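The alternatives without cluster 5 or 12, the scaling without S100a8 and S100a9 and the classes of at least 10 cells were chosen after the data were seen; the others were fixed beforehand. No paired analysis was possible because each group has 1 sample and tag numbers pair no animals. The 2 cell filters removed no cell and so tested nothing. The 2-fold rule and the molecule minimums cannot change a gene's ratio, nor the 2-fold rule a list's. Without these, of 52 comparisons of shares with alternatives fixed beforehand, 38 stayed within counting error, 12 moved and 2 reversed. For named genes 1135 of 1206 stayed, 70 moved and 1 reversed, and for lists 438 of 456 stayed and 18 moved. The gene comparisons include TMM scaling, under which no named gene was counted as moved. Yet it shifted uncentred log2 ratios, that of Il1rn in neutrophil-like cells from -0.665 to -0.347, and ended calls. The count of genes that stayed therefore says nothing about calls under TMM scaling.

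With the tags pooled, the differences in points were -3.13 for neutrophil-like, -2.05 for monocyte/macrophage-like, 2.14 for CD8 T cell-like and 2.04 for regulatory T cell-like cells, as tag 3 then weighs most. At resolution 0.5 CD8 T cell-like cells differed by 6.25 points, as both T cell classes merge there; regulatory T cell-like and NK cell-like cells gave no value. Leaving out 1 tag in turn gave -12.4 to -1.13 for neutrophil-like, -2.69 to 1.82 for monocyte/macrophage-like (reversed without tag 3, 1.82, and without tag 1, 0.0382), 1.55 to 4.89 for CD8 T cell-like and 1.40 to 4.53 for regulatory T cell-like cells. Neutrophil-like cells without cluster 12 differed by -7.48 points.

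Under TMM scaling 11 genes were higher and 21 lower in neutrophil-like cells, and 14 and 19 in the Lgals1-high cluster. With nearest tags 2-fold apart the counts were 3 and 19 in neutrophil-like cells and 4 and 4 in monocyte/macrophage-like cells, and 13 were lower in the Lgals1-high cluster. Without cluster 5, 3 genes were higher in neutrophil-like cells, and after removal of the 5% highest doublet scores 3 in monocyte/macrophage-like cells. Leaving out 1 tag, which makes the rule easier to pass, gave 12 to 20 higher and 52 to 70 lower in neutrophil-like cells, 7 to 48 and 29 to 48 in monocyte/macrophage-like cells, and 20 to 24 and 33 to 52 in the Lgals1-high cluster. The genes that reversed were Chil3 in neutrophil-like cells (log2 ratio -0.21 without cluster 5), Ccl3 in the Lgals1-high cluster (0.31 at resolution 0.5) and H2-Aa in CD8 T cell-like cells (-0.85 at resolution 0.5). Where no cause is named, the cause was not tested.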

Other observations

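All tests below were chosen after the results were seen, and the tests of free RNA and of macrophage RNA in the Lgals1-high cluster were redefined after their first values had been seen. At resolution 2.0 a conventional dendritic cell-like class separated from the monocyte/macrophage-like cells, with 3.57, 3.95, 3.21 and 6.72% of named leukocytes in tags 1 to 4. In it the integrin gene Itgae stood at 259, 262, 1201 and 669 CPM, the receptor gene Btla at 63.3, 117, 299.5 and 208 and the growth factor receptor Flt3 at 121, 641, 799 and 562. Few of its 75, 54, 199 and 82 cells carry these values. Itgae was found in 4, 3, 19 and 7 cells, Btla in 5, 7, 34 and 7 and Flt3 in 7, 10, 49 and 18. Most cells of the class carried Cd14 and Lyz2, so its name is uncertain. A mast cell or basophil-like class of 8, 7, 21 and 8 cells had the protease Cpa3 at 901, 6429, 15014 and 63638 and the IgE receptor subunit Fcer1a at 2515, 4822, 10253 and 22569.9. Its Il4 stood at 19298, 11384, 9543 and 1978 and its Il6 at 38220.4, 31206, 33797 and 9831, on too few cells for a comparison.

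Among genes counted in tags 2 to 4 alone, the Lgals1-high cluster had the interferon-induced genes Ifit3 (13.3, 221 and 134 CPM in tags 2, 3 and 4; 32.2% in 1 cell), Ifit2 (35.5, 72.6 and 73.2) and Gbp6 (589.7, 995 and 995) higher in both tags of the anti-PD-1 pool. S100a4 (31478, 17260.1 and 17071) and the cystine transporter gene Slc7a11 (146, 76.0 and 51.0) were lower there. In monocyte/macrophage-like cells Ifit2 (130.4, 78.6 and 54.7), Ifit3 (96.9, 47.0 and 29.1) and Rsad2 (175, 72.4 and 75.2) were lower, Gbp6 (237, 228 and 189.8) was not called, and the fixed interferon list had 0 of 5 called. These genes were chosen after their values were seen. In neutrophil-like cells Crip1 (1155, 152 and 128), Ccrl2 (15012, 8997 and 8962), Cxcl3 (4591, 3017.8 and 2648) and Siglecf (119, 74.5 and 74.4) were lower, and so were the epithelial genes Epcam (58.0, 30.003 and 25.7) and Msln (17.0, 7.91 and 6.87), whereas epithelial Cdh1 (36.8, 34.0 and 34.9) was not. Whether those epithelial molecules come from RNA of other cells or from neutrophils was not tested. Each of these comparisons sets tags 3 and 4 against tag 2 alone.

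The 14 genes lower in more than 1 of the 3 main classes could reflect a shift of the whole library rather than of the cells. In CD8 T cell-like, regulatory T cell-like and NK cell-like cells, which had no part in choosing them, the median over these genes of the mean uncentred log2 ratio was -0.998, as such a shift predicts, and 9 of 11 genes with a value lay below 0. A value here could rest on fewer than the 30 molecules that a measured gene needed. The 11 include Il6, whose value of -7.21 came from CD8 T cell-like cells alone and rests on 1 cell of tag 2. The 3 classes' own median genes averaged -0.06. Free RNA from 1 source stays open: the ratio of 30.32 in molecules per cell between the second highest class and the lowest decides nothing, as the second class can express the gene itself. A cartridge effect and an effect of anti-PD-1 on every cell type both stay open, since each pool is 1 cartridge.

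The class II and interferon genes higher in the Lgals1-high cluster could come from macrophage RNA or from a shift of the whole library. Macrophage RNA at the level of C1qa, C1qb or Trem2, with its own change between the pools, would make up at most 0.006522 of the differences of H2-Aa and H2-Eb1 and 0.00532 of those of Irf7 and Oas2. This argues against RNA of macrophages that carry these markers. RNA of cells poor in them was not tested. In tags 1 to 4 the dendritic cell-like cells had C1qa at 46.0, 0, 63.3 and 87.3 CPM and H2-Eb1 at 12709, 12296, 26831 and 24029. They did carry Trem2 (886, 860, 553 and 703). The median log2 ratio of -0.9234 of 9 macrophage markers in the cluster decides nothing, as they change in macrophages too. Irf7 and Oas2 had an uncentred median of 0.216 over their 7 measured values in the 5 other classes, against 1.24 in the cluster. This argues against a shift of the size seen in the cluster that is shared by all classes. A smaller shared rise stays open, as the interferon list's median lay 0.11 to 0.37 above the class median in the 5 other classes. H2-Aa and H2-Eb1 had a median of 0.3544 over 10 values in those classes, 3 above 0.8 and 2 below 0, so a shift shared by all classes stays open for them. A cartridge effect limited to this cluster, a different mix of cells within it and a response to anti-PD-1 stay open, and the last was not tested.

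Genes of other cell types, lower in neutrophil-like cells and the Lgals1-high cluster or higher in monocyte/macrophage-like cells, could come from RNA or cells caught with each class. For the 43 genes lower in neutrophil-like cells, RNA of the Lgals1-high cluster at the Epcam level would make up a median of 0.02832 of the difference. Macrophage RNA would make up a median of at most 0.05934, so RNA of these sources is too little for most of the genes. RNA of other cells was not tested and stays open. Eomes, for example, stood at 0.0122 molecules per cell in neutrophil-like cells of tags 1 and 2, against 11.7 in NK cell-like cells. Cluster RNA stays open for Lgals1 (0.518), for Fn1, S100a10, Ybx3, Lmna, Gata3, Cxcl1, Tmem97, Nrp1 and Trib2 (0.0730 to 1.47 over Epcam, Cdh1 and Msln), all picked by their shares at the Epcam level. Macrophage RNA stays open for the 11 genes besides C1qb, Arg1, H2-Aa and H2-Ab1 among them, that reach 0.2 by the C1qb level. For the 30 genes lower in the cluster, neutrophil RNA would make up a median of at most 0.01828, but by the S100a9 level at least 0.2 of the difference of 11 genes besides S100a9 and 0.8 of that of 9, with 0.175 to 1.10 for Il1rn, 0.280 to 1.91 for Cxcl2 and 0.679 to 4.70 for Ccl3 over 4 markers, so it stays open for those 11 and for S100a9. The 38 cells with at least 3 Cd8a molecules had 0.8963 times the Cd3 molecules per Cd8a molecule of CD8 T cell-like cells, and a higher median depth than the class (5562 against 2802 molecules), as CD8 T cells caught with macrophages would. Itgae and Btla were on average 11.74 times as abundant in the dendritic cell-like class as in the macrophages left at resolution 2.0 (767 against 140.1 and 208 against 11.6 CPM). Most cells of that class held no molecule of either gene, so a small part of it carries these values. Both genes stayed higher in those macrophages (33.0, 96.6, 203 and 173 and 3.96, 2.93, 17.8 and 12.6 in tags 1 to 4), so a change in macrophages themselves stays open. For Btla this rests on few molecules in tags 1, 2 and 4.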
